A study of Hordeum vulgare with 18 samples.

How the data were processed

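RNA was extracted with Trizol from shoots and roots of barley seedlings, and 400 ng of it was labelled with a Quick Amp kit for two-colour arrays, per the labels' protocols. Each array holds 43900 features, of which 42483 are probes of 60 bases with distinct sequences and the rest are controls. The authors deposited the scanner output of all 18 arrays, made with Feature Extraction 9.5.3.1 per the file headers. The submitters' processing notes name Agilent Feature Extraction 9.1, so the version is given differently in these sources. The deposited files hold mean and local background intensity per spot and channel, and log10 ratios of Cy5 over Cy3 that the scanner software computed after its own background subtraction and dye normalization. The deposited value table of the series holds the same log10 ratios: matched by feature number, the largest difference from the scanner files was 0. Its column medians lay between -0.00948 and 0.00558. Its scale and direction are therefore settled, and it was used as an alternative.

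The intensities were background-corrected with limma's normexp (offset 50) on the mean signal and the median local background, with all spots in the fit, and normalized within each array by loess with weight 0 for controls and outlier spots. Log2 ratios of later sample over 0 h sample were analysed. Outlier spots (at most 42 on an array) were left out and saturated spots (1 in all) were kept. A probe was tested if it was well above background in either channel on at least 4 of the 16 arrays at 3 h and 6 h, which left 39110 probes. The slope of observed on expected log ratios of the spike-in controls, per the file headers, lay between 0.831 and 0.919, where a slope below 1 means that the scanner software's ratios of these controls were compressed. Signal over background, not depth, limits what an array can show.

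Ratios were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, 1 coefficient per group, all 16 arrays in one fit) and Benjamini-Hochberg adjustment over the probes, with a threshold of 0.05. The 4 group ratios were tested against 0, and 6 h against 3 h and shoot against root as differences of group means. For shoot against root at 0 h, the Cy3 values after loess and Aquantile were averaged over the 3 h and 6 h arrays of each tissue and number, giving 4 shoot and 4 root values, and tested with limma. Each probe stood for itself, since each has its own identifier. A probe in a group where no array was well above background has only a bound there, taken from the mean of normalized log2 values against the higher of its own signal and the lowest signal well above background on each array. The 24 h arrays entered no test. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

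The design, the tests of the comparisons, most alternatives, 29 gene lists and the rule for naming genes were fixed before the data were examined. The rule took, per comparison, the probes with the largest change in each direction among those past the threshold with the same sign in all 4 replicates, and at 24 h the largest ratios among probes well above background in both channels. It applied to genes with a description. None of the 42483 probes has one in the files, and 0 of their identifiers matched the reference table of gene names, so the gene lists could not be tested, and by the same ranking at most 2 probes in each direction are named per comparison. For 864 probes the design gives 2 names. Probes of 1 clone that overlap by at least 20 bases (5523 pairs) served as a check of precision: the median absolute difference of their log2 group means was between 0.029 and 0.033 in the 4 groups, and over these pairs the root 3 h ratios correlated at 0.993 across probes.

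The replicate numbers in the labels run through all groups, so it was tested whether same-numbered arrays deviate together from their group means. Across probes, the correlation of same-numbered deviations lay between 0.26 and 0.692 for shoot 3 h with shoot 6 h, 0.632 and 0.729 for root 3 h with root 6 h, 0.17 and 0.401 for shoot with root at 3 h, and 0.199 and 0.337 at 6 h. All are above 0.1, so same-numbered arrays were taken to deviate together, and fits with the number as a block were run beside the unblocked ones. For shoot with root at 6 h this is less clear, since another numbering of the root replicates gave a higher mean correlation (0.271 against 0.268). The correlations do not show that the later samples were paired, since a shared 0 h sample, slide or scan batch could give them as well. The Cy3 signals of arrays of the same tissue and number correlated at 0.997 to 0.999 across probes, against 0.95 to 0.996 for other numbers of the tissue and 0.601 to 0.667 for shoot with root, so the 2 arrays of a number may share 1 extract at 0 h. The arrays lay on 5 slides. By the year of the scan date they formed 2 scan batches, the first holding replicate 1 and the second replicates 2 to 4. Scan days or sessions within a year were not told apart, so a scan batch here means a scan year. A slide held at most 1 array of a group, so within a slide no test was possible, and slide entered as a random block. Values without replicate 1 are those within the second scan batch.

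Alternatives were no background correction, median centring, Aquantile between arrays, the scanner software's log ratios, the deposited value table, no filter, a strict filter on all 16 arrays, the mean of the probes of a clone (names that differ only in the last number, 33377 names), only the arrays compared, an intensity trend in eBayes, blocks for replicate number and slide, and each replicate left out. Blocks for scan batch and 0 h sample, and the share of the 3 h response with its tests, were added after the data were seen. The procedure was tested on simulated data for 38959 probes with the measured spread per probe, a correlation of 0.257 within numbers and 200 changed probes. For root 3 h against 0 h, 42.3%, 86.0% and 93.7% of the probes changed by 0.5, 1 and 2 on the log2 scale were recovered, with 11 false calls. For root 6 h against 3 h the shares were 31.4%, 61.9% and 88.4% with 1 false call, and with the 0 h sample as a block 11.8%, 57.1% and 87.2% with 3. In the data, same-numbered root 3 h and 6 h deviations correlated at 0.632 to 0.729, well above the simulated 0.257. The recovery and false calls of these 2 fits therefore do not carry over to the data. For shoot minus root at 3 h the recovered shares were 9.52%, 54.5% and 91.7% with 6 false calls. For shoot against root at 0 h they were 1.35%, 56.5% and 84.4% with 1 false call. In every simulated comparison the noise was independent between probes, which the data are not shown to be. None of the counts of false calls therefore carries over to the data. The share of the 3 h response was simulated apart from this, with 1 in 3 probes changed and exactly 0.6 of each change present at 6 h. It was estimated as 0.598 ± 0.006 (SD over 4 replicates). The SD in the data was 0.053 in the root and 0.245 in the shoot, so the simulation does not give the precision of the measure there.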

Results

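Transcript levels were measured in the shoots and roots of untreated barley seedlings of the cultivar Haruna Nijo, a malting barley. Per the labels, 7 seeds were set on wet filter paper with 4.5 ml of water at 24 °C and an 8 h day, and 3 germinated seedlings were transferred after 4 days. Shoots and roots were then harvested separately at 0 h and after 3, 6 or 24 h of further incubation. Each of the 18 two-colour arrays set the later sample (Cy5) against the 0 h sample (Cy3) of the same tissue and replicate number. Shoot and root at 3 h and 6 h had 4 arrays each, which the labels call biological replicates, and each tissue had 1 array at 24 h. Between 83.4% and 88.6% of the 42483 probes were well above background in Cy3, and between 86.0% and 89.8% in Cy5. The number of arrays sets the precision of every value below, since array signals have no counting depth. The files pair no probe with a gene name or description, so each comparison names at most 2 probes that were higher and 2 that were lower, by the identifier of the array design. No dye swap was made, so in ratios to 0 h an effect of the dye on a probe cannot be separated from the effect of time.

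The first question was what changed in the shoot over the first hours of incubation. After 3 h the signals of Hv1054H21_1 and Hv2083E12_1 had risen most in the shoot. The log2 ratio of Hv1054H21_1 was 5.21 ± 2.19 (SD, n = 4), a 37-fold rise (limma adjusted p = 0.00595). The probe has the sequence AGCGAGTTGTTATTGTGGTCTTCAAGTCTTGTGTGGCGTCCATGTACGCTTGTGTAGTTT. Hv2083E12_1, with the sequence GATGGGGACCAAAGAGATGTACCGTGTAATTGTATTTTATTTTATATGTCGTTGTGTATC, had a log2 ratio of 5.21 ± 2.86 (SD, n = 4; limma adjusted p = 0.013). Replicate 1 stood far above the others for both, at 8.44 and 9.45, and without replicate 1 the ratios of Hv1054H21_1 and Hv2083E12_1 were 4.13 and 3.79. Hv2083E12_1 had 5.85 both without replicate 4 and with scan batch as a random block. Hv3085E19_1 fell most, by 3.68 on the log2 scale (SD 0.56, n = 4), which is 12.8-fold (limma adjusted p = 0.000545). Its sequence is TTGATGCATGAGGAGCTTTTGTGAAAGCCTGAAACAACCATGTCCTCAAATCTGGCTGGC. Hv2104L08_1 fell by 2.56 (SD 0.61, n = 4), or 5.89-fold (limma adjusted p = 0.000849). All 4 were well above background in both channels on every shoot array at 3 h. In the root at 3 h, Hv1054H21_1 and Hv2083E12_1 had ratios of 0.95 ± 2.64 and 0.86 ± 2.73 that did not pass (limma adjusted p = 0.54 and 0.642).

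Of the 39110 probes tested, 7392 (18.9%) passed limma's adjusted p of 0.05 in the shoot at 3 h, 3989 higher and 3403 lower. Most changes were small. At least 2-fold differences were seen for 676 of the called probes, of which 524 were higher and 152 lower. The majority turned with the scanner software's log ratios, with 3575 higher and 3934 lower, and 1263 called probes differed at least 2-fold. The count was 4542, 2826 and 4023 without replicate 2, 3 and 4 and 3661 when the spread was taken from the shoot 3 h arrays alone, and Hv2083E12_1 lost its call without replicate 2 (limma adjusted p = 0.0623). Median centring in place of loess gave 11746. Within the later scan batch (replicates 2 to 4) 5543 probes passed, and 4934 with scan batch as a random block; the earlier batch held 1 replicate.

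After 6 h the same 2 probes led the rise in the shoot. The log2 ratio of Hv2083E12_1 was 6.34 ± 2.45 (SD, n = 4), an 80.8-fold rise (limma adjusted p = 0.00536), and that of Hv1054H21_1 was 6.29 ± 1.67 (SD, n = 4; limma adjusted p = 0.00241). Without replicate 1 these were 5.13 and 5.47, and with scan batch as a random block 6.98 and 6.80. Hv3085E19_1, again the probe with the lowest ratio among those named, fell by 2.84 (SD 0.96, n = 4; limma adjusted p = 0.00285). Hv2141C24_1 fell by 2.12 (SD 0.65, n = 4; limma adjusted p = 0.00393), and in the root it fell by 1.96 (SD 1.06) at 3 h and by 1.68 (SD 1.09) at 6 h (n = 4 each; limma adjusted p = 0.00214 and 0.0124). In all, 5892 probes passed at 6 h, 3111 higher and 2781 lower, and 536 of them differed at least 2-fold (409 higher, 127 lower). Under the scanner software's log ratios 2686 were higher and 2747 lower, 938 called probes differed at least 2-fold, and the ratio of Hv2141C24_1 was -3.13. The count fell to 2456 without replicate 2, 2306 without replicate 3 and 3042 with the shoot 6 h arrays alone, and rose to 10587 with median centring. Hv2083E12_1 lost its call without replicate 2 (limma adjusted p = 0.0523). Within the later scan batch 4375 probes passed, and 3918 with scan batch as a random block.

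The same question was asked of the root. After 3 h, Hv2115D22_1 and Hv2004D15_2 had risen most. Hv2115D22_1 had a log2 ratio of 5.24 ± 0.47 (SD, n = 4), a 37.7-fold rise (limma adjusted p = 7.65e-06). Its sequence is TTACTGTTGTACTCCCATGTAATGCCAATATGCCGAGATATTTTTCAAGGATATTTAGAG. Hv2004D15_2 had a ratio of 5.10 ± 0.78 (SD, n = 4), or 34.2-fold (limma adjusted p = 5.94e-08), with the sequence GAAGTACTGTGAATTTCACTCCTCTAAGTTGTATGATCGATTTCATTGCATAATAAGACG. The 2 probes that fell most carry the name of 1 clone and overlap by 43 bases, so they are not independent. Hv2127O24_2 fell by 3.39 (SD 0.15, n = 4), or 10.4-fold, and Hv2127O24_1 by 3.33 (SD 0.17, n = 4; limma adjusted p = 1.87e-05 and 2.15e-05). The sequence of Hv2127O24_2 is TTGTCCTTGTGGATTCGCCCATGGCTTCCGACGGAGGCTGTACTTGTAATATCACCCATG.

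In the root at 3 h, 14238 probes (36.4% of those tested) passed, 7708 higher and 6530 lower, and 2428 of these differed at least 2-fold (1377 higher, 1051 lower). The count was 8628 without replicate 2, 8631 without replicate 3 and 7923 with the root 3 h arrays alone. Hv2115D22_1 stood at 6.11 and Hv2004D15_2 at 5.81 with the scanner software's log ratios. Within the later scan batch 12875 probes passed, and 11731 with scan batch as a random block.

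After 6 h the probe with the highest ratio in the root was Hv2056I16_1, at 4.10 ± 0.76 (SD, n = 4; limma adjusted p = 1.35e-05), but its 0 h signal was well above background on only 1 of the 4 arrays. Its value was 6.50 with the scanner software's log ratios. Hv2056I16_1 was also higher in the shoot, at 2.47 ± 0.72 after 3 h and 2.15 ± 0.84 after 6 h (SD, n = 4; limma adjusted p = 0.000592 and 0.0015). Hv2081J19_1 had a root ratio of 3.64 ± 1.44 at 6 h (SD, n = 4), a 12.5-fold rise (limma adjusted p = 0.000979). Hv2138E02_1 fell by 3.11 (SD 1.52, n = 4), or 8.65-fold, and Hv2029P20_1 fell by 3.01 (SD 1.57, n = 4; limma adjusted p = 0.000476 and 0.0216). In all, 7186 probes passed in the root at 6 h, 3679 higher and 3507 lower, and 1224 differed at least 2-fold (614 higher, 610 lower). The scanner software's log ratios gave 1920 of these.

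Without replicate 2 the root ratio of Hv2081J19_1 at 6 h was 4.25, and without replicate 1 that of Hv2138E02_1 was -3.83. Among the comparisons of 3 h and 6 h with 0 h, the root at 6 h leaned most on the spread shared by the 4 groups. With the root 6 h arrays alone 622 probes passed, and Hv2081J19_1, Hv2138E02_1 and Hv2029P20_1 did not (limma adjusted p = 0.0573, 0.0742 and 0.0807). The count was 3328 without replicate 2, 2266 without replicate 3 and 12672 with median centring, and Hv2029P20_1 also lost its call without replicate 2 or 3 (limma adjusted p = 0.176 and 0.168) and with scan batch as a random block (limma adjusted p = 0.066). Within the later scan batch 5614 probes passed, with the majority turned (2647 higher, 2967 lower), and 4849 with scan batch as a random block.

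**Figure D1:**
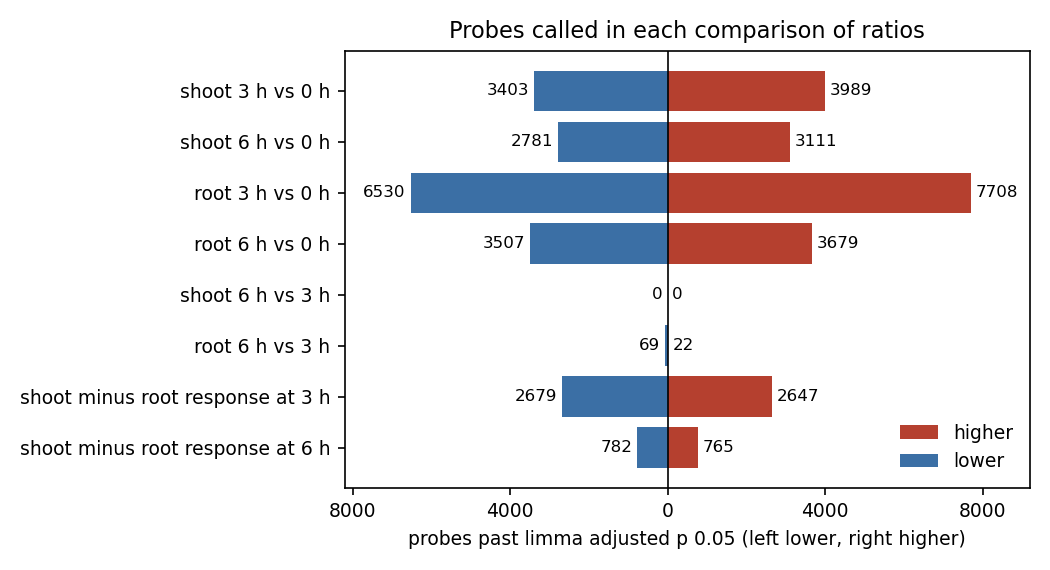
Number of probes (horizontal axis) past limma's adjusted p of 0.05 in 8 comparisons of ratios, with lower probes as bars to the left of 0 and higher probes to the right. The root at 3 h has the longest bars (7708 higher, 6530 lower), and no probe passed between 6 h and 3 h in the shoot.

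Setting 6 h against 3 h in each tissue asks how the response moved on, and any dye effect common to the arrays cancels. In the root, Hv2004D15_2 and Hv2004D15_1, 2 probes of 1 clone that overlap by 50 bases, were lower at 6 h than at 3 h. The ratio of Hv2004D15_2 went from 5.10 ± 0.78 to 2.68 ± 0.67 (SD, n = 4), a difference of -2.42 (limma adjusted p = 0.0312), and that of Hv2004D15_1 from 5.08 ± 0.79 to 2.83 ± 0.76 (SD, n = 4), a difference of -2.25 (limma adjusted p = 0.0365). Hv2115F19_1 had fallen by 2.33 (SD 0.66, n = 4) at 3 h and stood at -0.58 ± 0.61 (SD, n = 4) at 6 h, a difference of 1.75 (limma adjusted p = 0.0397). Hv2098K20_1 went from -2.17 ± 0.60 to -0.64 ± 0.25 (SD, n = 4), a difference of 1.53 (limma adjusted p = 0.0331). All 4 differences had the same sign in 4 of 4 replicates. At 6 h all 4 probes were thus nearer to their 0 h level than at 3 h. In the single root array at 24 h (replicate 1), Hv2098K20_1 stood at -2.558, further from 0 h than in that replicate at 3 h (-2.085). Hv2004D15_2, Hv2004D15_1 and Hv2115F19_1 stood at 1.88, 1.83 and -0.35 there, nearer than in that replicate at 3 h.

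In the root 91 probes passed between 6 h and 3 h, 22 higher and 69 lower at 6 h. In the shoot no probe passed with limma, and 598 had an unadjusted p under 0.05. Chance alone would give a share of 0.05 of the 39110 probes tested, and 598 is fewer than that. Same-numbered arrays of a tissue deviated together, and with the replicate block 877 root probes and 0 shoot probes passed. With the 0 h sample as a block, a fit added after the data were seen, 4273 root probes passed (1337 higher, 2936 lower). In the shoot again 0 passed in that fit, but 3457 had an unadjusted p under 0.05, more than a share of 0.05. The counts of 0 therefore do not show that the shoot stood still between 3 h and 6 h. Of the 7708 root probes higher at 3 h, 2079 came back towards 0 h by 6 h in that fit and 18 moved further away, and of the 6530 lower ones 985 came back and 24 moved further away. Part of this return is built in, since probes called at 3 h were picked on the values they are then compared with. The unblocked root count was 0 without replicate 1, 2 or 3, 0 with the root arrays alone, 14 (42.9% higher against 24.2%) with the scanner software's log ratios, 605 with slide as a random block and 398 with scan batch as a fixed block. None of the 4 named probes kept its call without replicate 1, 2 or 3 (limma adjusted p from 0.0576 to 0.573), with the root arrays alone or with the scanner software's log ratios, and without replicate 4 Hv2115F19_1 alone kept its call.

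A measure without that selection was added after the counts were seen. For each replicate, the covariance of its 6 h ratios with the mean 3 h ratios of the other 3 replicates was divided by the same covariance of its own 3 h ratios. This gives the share of the 3 h response that was present at 6 h, and a dye effect on single probes would bring it nearer to 1. Over 38959 probes the share was 0.632 ± 0.053 in the root (SD, n = 4) and 0.887 ± 0.245 in the shoot (SD, n = 4). It was below 1 in 4 of 4 root replicates and in 3 of 4 shoot replicates. An exact sign-flip test against 1 gave a two-sided p of 0.125 in the root, the smallest that 4 values allow, and 0.5 in the shoot. The tissues differed by 0.255, with a two-sided p of 0.0286 in an exact permutation test of the 8 values, the smallest it can give. Paired by number, exact sign flips gave 0.125. Each value uses the mean 3 h ratios of the other 3 replicates, so the 4 values of a tissue are not independent. The SDs and p-values of the share are approximate for that reason. The difference rests largely on replicate 2, whose shoot value was 1.25. Without replicate 2 the share was 0.685 in the root and 0.784 in the shoot, a difference of 0.099 (permutation p = 0.2), and without replicate 1, the earlier scan batch, 0.632 and 1.028, a difference of 0.396 (permutation p = 0.1, the smallest that 3 replicates allow). The scanner software's log ratios gave a difference of 0.216 (exact permutation p = 0.0857).

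**Figure D2:**
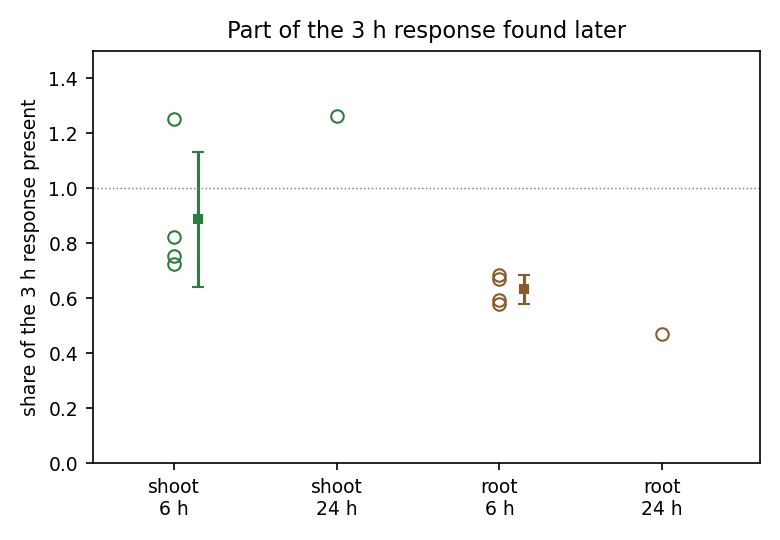
Share of the 3 h response present later (vertical axis), per replicate as open circles with the mean and SD beside them as a square with bars, for shoot and root at 6 h (4 replicates) and at 24 h (replicate 1). The 4 root values at 6 h lie between 0.579 and 0.685, all below the 4 shoot values, which start at 0.723.

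Whether shoot and root responded differently was tested as the difference between their ratios, in which a common dye effect also cancels. At 3 h, Hv2115D22_1 and Hv2004D15_2, which led the rise in the root, had the lowest differences among the probes named. The shoot ratio of Hv2115D22_1 was 0.31 ± 1.11 and its root ratio 5.24 ± 0.47 (SD, n = 4), a difference of -4.93 (limma adjusted p = 0.00118), or -5.69 with the scanner software's log ratios. For Hv2004D15_2 the fitted difference was -4.95 (limma adjusted p = 1.1e-05), but in the shoot at 3 h it was well above background on 0 of 4 arrays in Cy3 and 1 of 4 in Cy5. Its shoot ratio there is largely one of background, so the size of this difference is not a measured difference in response. In the other direction, Hv2127O24_2 had a shoot ratio of 0.19 ± 0.26 against -3.39 ± 0.15 in the root (SD, n = 4), a difference of 3.57 (limma adjusted p = 0.00119). Hv1115L08_1 had 1.87 ± 1.65 in the shoot and -1.78 ± 1.54 in the root (SD, n = 4), a difference of 3.64 (limma adjusted p = 0.038), though neither ratio passed by itself (limma adjusted p = 0.102 and 0.0819). In all, 5326 probes passed at 3 h, 2647 with the higher ratio in the shoot and 2679 with the higher ratio in the root, and 1665 of them by at least 2-fold (1009 with the higher ratio in the shoot, 656 in the root).

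With the replicate block 8785 probes passed at 3 h, and 8702 with slide as a random block. The count was 3090, 2041 and 1173 without replicate 1, 2 and 3 and 2978 with the 3 h arrays alone, and Hv1115L08_1 lost its call there (limma adjusted p = 0.0571) and without replicate 2, 3 or 4 (limma adjusted p = 0.163, 0.154 and 0.0522), where without replicate 4 its difference was 4.46. With scan batch as a fixed block 7287 probes passed, and the 3090 without replicate 1 are those of the later scan batch.

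At 6 h Hv2115D22_1 again had the lower ratio in the shoot, at 0.06 ± 1.22 against 3.14 ± 1.47 in the root (SD, n = 4), a difference of -3.08 (limma adjusted p = 0.0335). Hv1056P15_1 had -0.06 ± 1.14 in the shoot and 2.74 ± 0.77 in the root (SD, n = 4), a difference of -2.81 (limma adjusted p = 0.0174). Hv2102C12_1 had 1.31 ± 2.22 in the shoot and -2.43 ± 1.44 in the root (SD, n = 4), a difference of 3.74 (limma adjusted p = 0.0458). Hv3008F16_1 had 1.05 ± 0.52 in the shoot and -2.54 ± 0.70 in the root (SD, n = 4), a difference of 3.59 (limma adjusted p = 0.0103). In all, 1547 probes passed, 765 with the higher ratio in the shoot and 782 with the higher ratio in the root, and 627 by at least 2-fold (375 with the higher ratio in the shoot, 252 in the root).

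With the replicate block 3529 probes passed at 6 h, 3122 with slide as a random block and 2630 with scan batch as a fixed block. The count was 177, 56 and 902 without replicate 2, 3 and 4, 738 with the 6 h arrays alone and 1420 within the later scan batch (869 with the higher ratio in the shoot, 551 in the root). Median centring gave 2609, of which 59.9% had the higher ratio in the shoot against 49.5% with loess. Without replicate 2 or 3 each of the 4 named probes lost its call (limma adjusted p from 0.0717 to 0.277). Hv2102C12_1 and Hv1056P15_1 lost theirs without replicate 4 too (limma adjusted p = 0.194 and 0.0517). With the 6 h arrays alone Hv2102C12_1, Hv2115D22_1 and Hv1056P15_1 did not pass (limma adjusted p = 0.141, 0.103 and 0.0604). With the scanner software's log ratios Hv2102C12_1 and Hv2115D22_1 did not pass (limma adjusted p = 0.056 and 0.0515), and the differences of Hv2115D22_1 and Hv1056P15_1 were -3.73 and -3.49. The difference of Hv2115D22_1 was -3.73, -2.27 and -3.68 without replicate 1, 2 and 4, that of Hv2102C12_1 was 4.51 without replicate 2, and that of Hv3008F16_1 was 2.99 without replicate 1.

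**Figure D3:**
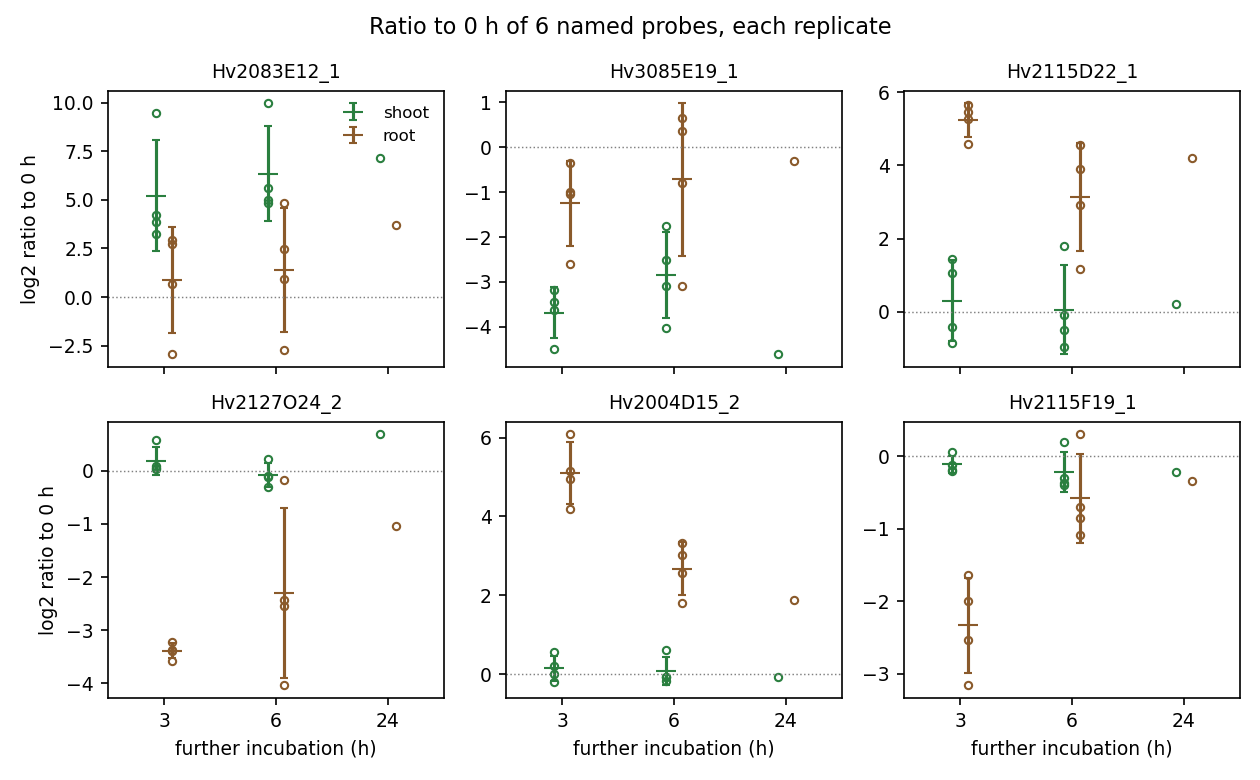
Log2 ratio to 0 h (vertical axis) of 6 named probes after 3, 6 and 24 h of further incubation (horizontal axis), with 1 open circle per replicate, green for shoot and brown for root, and dashes with bars for the mean and SD of 4 replicates. Hv2115D22_1 and Hv2004D15_2 stand above 4 in every root array at 3 h, and Hv2083E12_1 stands above 3 in every shoot array at 3 h and 6 h.

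Many probes moved the same way in both tissues. At 3 h, 2149 probes were higher in both shoot and root, against 786 for independent lists of these sizes, and 1305 were lower in both, against 568. Opposite calls were fewer than for independent lists, with 177 higher in shoot and lower in root (666) and 134 lower in shoot and higher in root (671). At 6 h, 1239 probes were higher in both (293) and 709 lower in both (249). Shoot and root had separate 0 h samples, but a dye effect would be the same in both tissues and same-numbered arrays deviated together, so the excess is not shown to be a common response.

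The 0 h samples also allow shoot and root to be compared directly, since both carried Cy3. Shoot and root differed far more from each other than either changed over time. Hv1089J16_2 was higher in the shoot by a fitted log2 difference of 10.05 ± 0.50 (SD, n = 4; limma adjusted p = 1.99e-08), and Hv2031M03_1 by 9.87 ± 0.24 (SD, n = 4; limma adjusted p = 7.77e-10). In the root these 2 were well above background on 6 and on 2 of 8 arrays, so the sizes rest on signals near background and hold only roughly. With processed Cy3 signals scaled to the 75th percentile they were 12.13 and 13.20. Hv2022H16_1, with the sequence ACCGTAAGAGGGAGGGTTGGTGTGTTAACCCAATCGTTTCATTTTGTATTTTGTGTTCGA, was at least 1160-fold higher in the root, and Hv2081M21_1 at least 840-fold (limma adjusted p = 1.94e-09 and 6.4e-10). Neither was well above background on any of the 8 shoot arrays, so each fold is a bound, set against the lowest signal well above background on those arrays. In the root after incubation Hv2081M21_1 fell by 1.93 (SD 0.30) at 3 h and fell by 2.26 (SD 0.26) at 6 h (n = 4 each; limma adjusted p = 1.05e-07 and 4.27e-08). At 0 h 27821 probes (71.1%) passed, 9841 higher in shoot and 17980 higher in root, and 15521 of them differed at least 2-fold, 7150 higher in shoot and 8371 in root. The median difference over all tested probes was -0.35, and the split between tissues is relative to the scaling of the arrays. Within the later scan batch 30796 probes passed, and 31623 with scan batch as a fixed block.

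The 24 h arrays extend the course for replicate 1 of each tissue, with no replicate check and no test. In the shoot array Hv2083E12_1 and Hv1054H21_1 again had the highest ratios, 7.15 (142-fold) and 6.67 (101-fold). Both lay below the ratios of the same replicate at 3 h (9.45 and 8.44) and 6 h (9.97 and 8.75). Hv2045I20_1 and Hv3062P03_1 had the lowest, -5.37 and -4.61, after means of -2.25 ± 1.20 and -1.83 ± 1.72 at 3 h (SD, n = 4). In the root array Hv2100L10_1 and Hv3126E17_1 had the highest ratios, 6.72 and 6.39. Hv2100L10_1 varied widely between replicates before that, at -0.179 ± 2.525 at 3 h and 2.369 ± 3.954 at 6 h (SD, n = 4). The ratio of Hv3126E17_1 had been 0.11 ± 0.10 at 3 h and 0.47 ± 0.92 at 6 h (SD, n = 4). Hv1143J11_1 and Hv2057P20_1 had the lowest, -5.88 and -4.64, and both varied widely between replicates at 3 h (-2.64 ± 3.21 and 0.12 ± 3.63, SD, n = 4). In the shoot 2199 probes were at least 2-fold higher and 2114 at least 2-fold lower at 24 h, against 1622 and 890 in the shoot array of replicate 1 at 3 h and 2280 and 1120 at 6 h. In the root the counts were 1354 and 1188 at 24 h, 2362 and 2712 at 3 h and 1857 and 1571 at 6 h. The share of the 3 h response present at 24 h was 1.262 in the shoot and 0.471 in the root for this replicate. The scanner software's log ratios gave -5.60 and -6.11 for Hv2045I20_1 and Hv3062P03_1, which turns their order, 7.77 for Hv3126E17_1, and -7.08 and -5.24 for Hv1143J11_1 and Hv2057P20_1. With these ratios, 3943 root probes differed at least 2-fold at 24 h, against 2542 here.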

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

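Of the tests reported here, those on ratio compression, the shared slide and the dye effect in the shoot were chosen only after the result was seen. The share of the 3 h response with its permutation and sign-flip tests, the other numberings of the replicates, and the blocks for 0 h sample and scan batch, were added after the data were seen.

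By the gap between 1 replicate and the other 3, in each tissue and at each time, 8 of the named probes stood out. Replicate 1 of Hv2083E12_1 had a shoot log2 ratio of 9.45 at 3 h, with the others between 3.26 and 4.24, and of 9.97 at 6 h, with the others between 4.82 and 5.58. Replicate 4 of Hv2056I16_1 had a root ratio of 2.96 at 6 h, with the others between 4.42 and 4.53. In the root at 3 h replicate 1 had 4.31 for Hv2081J19_1, with the others between 0.80 and 1.17, and -0.38 for Hv2141C24_1, with the others between -2.60 and -2.29. The rest lay in the shoot near 0: replicate 2 at 3 h for Hv2127O24_2 (0.58) and Hv2127O24_1 (0.63), which overlap, and at 6 h replicate 3 for Hv2004D15_2 (0.61) and replicate 4 for Hv2115F19_1 (0.19). Chance alone marks about 1 in 20 groups by this measure, and 9 of 118 groups were marked.

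Responses differed between the tissues, by the test of the difference itself, for 5326 probes at 3 h and 1547 at 6 h. At 3 h the named probes were Hv1115L08_1 (3.64), Hv2127O24_2 (3.57), Hv2004D15_2 (-4.95) and Hv2115D22_1 (-4.93), each the shoot minus the root log2 ratio. The value of Hv2004D15_2 rests on a shoot signal well above background on 0 of 4 arrays in Cy3 and 1 of 4 in Cy5. At 6 h they were Hv2102C12_1 (3.74), Hv3008F16_1 (3.59), Hv2115D22_1 (-3.08) and Hv1056P15_1 (-2.81). Between 6 h and 3 h in the root, 91 probes differed, and the named ones were Hv2115F19_1 (1.75), Hv2098K20_1 (1.53), Hv2004D15_2 (-2.42) and Hv2004D15_1 (-2.25). The share of the 3 h response present at 6 h differed between shoot and root by 0.255 (permutation p = 0.0286), but by 0.099 without replicate 2 (p = 0.2), and paired by number the p was 0.125.

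Other groupings of the arrays were counted for each comparison, over probes measured on all 16 arrays. For shoot minus root, the real split was the only 1 of 35 to give as many probes at 3 h (5290, with at most 1 in any other split). At 6 h it was so as well (1537, at most 1). For shoot against root at 0 h, 1 of 35 splits gave as many and the highest other gave 38. A share of 1 in 35 is the smallest these splits can give. It applies only to unpaired arrays, whereas same-numbered shoot and root arrays deviated together. Where only the 8 splits that part all pairs are counted, the others gave 0 in these 3 comparisons. As 8 splits are too few for a share under 0.05, chance is not excluded once the pairs are kept. For the ratios to 0 h, turning the sign of arrays gives only 8 distinct choices, too few for a share under 0.05. The real choice was the 1 with the most probes in each case, and the highest other gave 2 for shoot 3 h (7392 in the full set), 150 for shoot 6 h (5892), 0 for root 3 h (14238) and 0 for root 6 h (7186). For 6 h against 3 h in the root, 6 of 35 splits gave as many as the real 90, so a chance split cannot be excluded without the pairing. The highest gave 2245 and set replicates 1 and 4 against replicates 2 and 3, which points to a structure of the samples that does not follow the scan years. Among the 8 splits that part all pairs, the others gave 0, and with the 0 h sample as a block the real 4235 stood against at most 0 in the other swaps. In the shoot the real count was 0, so all 35 splits gave as many, up to 130 for replicates 1 and 4 against 2 and 3, and at most 0 for other splits that part all pairs.

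The first pattern weighed is that 890 probes were called higher and 480 lower in all 4 comparisons with 0 h, against 5.88 and 3.62 for independent lists. With the group means removed, the signs of whole replicates were turned in 7 ways, which keeps the shared 0 h samples and removes any effect. The most were called with replicates 2 and 3 turned, at 4 higher and 391 lower. Turning replicates 1 and 4 instead reverses every ratio and so swaps these counts. The 890 and the 480 are thus both set against 391, and the 480 stand less clear of the shared samples. A dye effect on each probe as the whole cause of the root ratios is argued against, since for probes picked on 3 replicates the median ratio of the replicate left out was smaller at 6 h than at 3 h in the root by quotients up to 0.796 (mean 0.668, SD 0.123, n = 4), and base composition showed a Spearman rho of only -0.039 across probes with the mean ratio. In the shoot the mean quotient was 0.978 (SD 0.223, n = 4), so a dye effect and a lasting response cannot be told apart there. A response to the further incubation shared by both tissues (0.668 in the root) cannot be told apart from a dye effect plus a change in time, since Cy5 always carried the later sample.

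The second pattern is that root ratios were smaller at 6 h than at 3 h. Stronger ratio compression on the 6 h arrays is argued against by spike-in slopes at 6 h of at least 0.993 of those at 3 h in each replicate. Dim probes are argued against by a share kept of 0.601 (SD 0.088, n = 4) among the brightest 9739 of the 38959 probes, and a single replicate by a mean share of at most 0.685 whichever replicate is left out. As a hypothesis, part of the root response may be a short-lived reaction to the transfer of the seedlings at the start of the incubation. The design held no seedlings left in place, so this was not tested, and time of day under the 8 h day stays open as well.

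The third pattern is that same-numbered shoot and root arrays deviate together. Over all 4 replicates, the real numbering of the root replicates gave the highest mean correlation of 24 (0.283, the highest other 0.226), but at 6 h alone 1 other gave more (0.271 against 0.268). The 2 scan batches cannot be told apart from a pairing of the samples: within the second batch same-numbered deviations exceeded those of other numbers by 0.32 (0.216 against -0.104), past the bound set in advance, but centring 3 replicates forces the second mean below 0, 3 replicates have only 6 numberings, and at 6 h 1 other numbering gave more (0.196 against 0.189). The shared slide stays open: the replicate 1 root array on another slide correlated at 0.346 with the shoot arrays of its number, and the one on their slide at 0.309, but this is 1 replicate, and for the rest slide and number cannot be told apart. Growth of the shoots and roots of 1 number in the same dishes would give the same values and was not tested.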

How the results depend on the processing

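The blocks for scan batch and 0 h sample, and the share of the 3 h response with all its settings, were chosen after the data were seen. No named probe changed direction under any alternative run. No background correction, the filters, the mean of the probes of a clone and an intensity trend kept every count of called probes within 1.5 times, and Aquantile leaves ratios as they are by construction. Shoot against root at 0 h stayed between 23192 and 31977 probes under every alternative run for that comparison. Median centring gave 11746 (shoot 3 h), 10587 (shoot 6 h) and 12672 (root 6 h) probes against 0 h and 2609 for shoot minus root at 6 h, with the cause not tested. The count of called probes at 2-fold or more rose with the scanner software's log ratios from 676 to 1263 (shoot 3 h), 536 to 938 (shoot 6 h) and 1224 to 1920 (root 6 h), the last falling to 353 with its own arrays alone and 787 without replicate 3. For shoot minus root it went from 1665 to 1083 and 718 at 3 h without replicate 2 and 3, and at 6 h from 627 to 1102 with median centring, 1017 with the replicate block, 963 with slide as a block, 362 with the 6 h arrays alone and 136 and 49 without replicate 2 and 3. The scanner software's log ratios and the deposited value table gave 14 probes for root 6 h against 3 h, and the former 3943 at 24 h in the root; the cause was not tested. With only the arrays of the groups compared, which leaves fewer arrays to estimate the spread, the counts were 3661 (shoot 3 h), 3042 (shoot 6 h), 7923 (root 3 h), 622 (root 6 h), 0 (root 6 h against 3 h), 2978 (shoot minus root at 3 h) and 738 (at 6 h).

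With the replicate block, root 6 h against 3 h gave 877 probes and shoot minus root 8785 at 3 h and 3529 at 6 h, and the pairing changed no other call by over 1.5 times. Slide as a random block gave 605, 8702 and 3122 for these 3. Scan batch as a block gave 3918 for shoot 6 h, 398 for root 6 h against 3 h and 2630 for shoot minus root at 6 h. The 0 h sample as a block gave 4273 for root 6 h against 3 h.

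Leaving out 1 replicate gave 2826 to 5543 probes for shoot 3 h, 2306 to 4375 for shoot 6 h, 8628 to 13429 for root 3 h, 2266 to 6085 for root 6 h, 0 for shoot and 0 to 106 for root 6 h against 3 h, 1173 to 4995 for shoot minus root at 3 h, 56 to 1420 at 6 h and 23687 to 30796 at 0 h. The share of the 3 h response present at 6 h moved by at most 1 SD under each setting run, in the root furthest without replicate 2 (0.632 to 0.685, SD 0.053). The difference in share between the tissues kept its direction, at 0.099 to 0.396 with 1 replicate left out, where 3 values per tissue cannot give a permutation p under 0.1, and at 0.216 (exact permutation p = 0.0857) with the scanner software's log ratios, with the cause not tested. Of the values of named probes under alternatives, 464 stayed past the threshold and 56 kept their direction without passing it. These counts include Aquantile, which could not change a ratio. They also include the deposited value table, which repeats the scanner software's log ratios, so the tally overstates how well the calls hold. The camera and fry tests of the gene lists were not run, since no list has a member here. Signal over background limits probes in the tissue where they are dim. Bounds are given for Hv2022H16_1 and Hv2081M21_1, and the fitted values of other dim probes hold only roughly.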

Other observations

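Of the 7150 probes at least 2-fold higher in the shoot at 0 h, 677 (9.47%) were called higher and 1823 (25.5%) lower in the root after 3 h. Of the 8371 probes at least 2-fold higher in the root, 1960 (23.4%) were called higher and 1192 (14.2%) lower there, close to the 5071 (21.5%) and 3515 (14.9%) of the 23589 probes in neither class. In the shoot at 3 h, 544 (7.61%) of the shoot-higher probes were called higher and 1174 (16.4%) lower, against 1104 (13.2%) and 397 (4.74%) of the root-higher ones and 2341 (9.92%) and 1832 (7.77%) of those in neither class. No test compared the classes.

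Since the 0 h signal enters both the tissue class and the ratio, the classes were also set on 3 replicates and the median ratio read in the replicate left out. In the root the shoot-higher class had a median log2 ratio of -0.106 ± 0.054 at 3 h and -0.075 ± 0.058 at 6 h (SD, n = 4), below 0 in 4 of 4 replicates at both times. The root-higher class and the probes in neither class had 0.030 ± 0.039 and 0.030 ± 0.012 in the root at 3 h (SD, n = 4). At 6 h they had 0.045 ± 0.018 and 0.017 ± 0.010 (SD, n = 4), each above 0 in 4 of 4 replicates. In the shoot the shoot-higher class had -0.069 ± 0.098 and -0.101 ± 0.136 (SD, n = 4), above 0 in 1 of 4 replicates at both times, so its shift was within about the spread between replicates. With 4 values an exact sign-flip test cannot give a two-sided p under 0.125. The shift is small beside the changes of single probes.

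As a share of the covariance within the own tissue, the covariance of shoot ratios with root ratios of other replicates was 0.706 ± 0.104 at 3 h and 0.589 ± 0.115 at 6 h (SD, n = 4). From the root side it was 0.313 ± 0.031 and 0.376 ± 0.034 (SD, n = 4). A dye effect on single probes would be the same in both tissues and would bring these values nearer to 1, so they do not measure a common response.

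Probes Hv1054H21_1 and Hv2083E12_1 moved unequally between root replicates as well, with SDs of 2.64 and 2.73 on the log2 scale at 3 h and 3.00 and 3.18 at 6 h (n = 4). In the single root array at 24 h they stood at 3.56 and 3.71.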
